A study of Mus musculus with 2 samples.

How the data were processed

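Total RNA of sorted CD45-negative lymph node cells from normal mice and from mice with a 4T1 mammary tumor was amplified, labeled with Cy3 and hybridized to 2 one-color Agilent mouse arrays, per the labels' protocols. Groups were taken from the labels, which give 1 sample to each. Both arrays lie on 1 slide and were scanned together, per the file headers, so slide and scan do not separate the groups.

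The deposited scanner files hold linear spot intensities, with background subtracted by Agilent Feature Extraction (version 12.0.3.1 and protocol GE1_1200_Jun14 per the file headers). The submitters' processing notes name Feature Extraction version 10.7 and limma, with no role or order. The positions of probes are on the mm9 build, per the file headers. The authors' deposited value table holds log2 values with no stated scale. Each of its columns correlated across probes with the log2 processed signal of the same array (r = 0.9999), its column medians were 4.85 and 4.86, and its sorted columns differed by at most 0.17, so the table follows quantile-normalized log2 signals, with no centering by gene, and a one-color value has no ratio direction. The steps the authors took to make that table stay unknown, and it was used as an alternative only.

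For the main values, the log2 processed signal of each spot was reduced by the 75th percentile over the 59305 non-control spots of its array. Spots marked as non-uniform or as outliers among replicate spots were left out, along with control spots. Spots of a probe were averaged, and a gene was represented by its probe with the highest mean over both arrays. A probe counted as above background where at least 50% of its spots carried the software's well-above-background mark. No non-control spot was saturated. The 75th percentile of the signal was 374 on the normal array and 358 on the tumor-draining array. Of the probes, 32992 were named through a RefSeq accession in a GRCm38.p6 gene table, 10224 by a current symbol and 520 by a synonym of 1 gene, and 12867 kept the name in the files. This gave 37008 gene names. Coordinates come from the array files alone, which do not state exon or UTR.

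Differences are tumor-draining minus normal on the log2 scale, and no test was run, since each group has 1 array. For a gene above background on 1 array only, the fold is a bound: the bright value against the higher of the dim value and the lowest signal among probes above background on the dim array. The 32 gene lists, of 5 to 25 genes, the naming rule and the alternatives were fixed before the data were examined. A list's shift is the median difference of its members above background on at least 1 array minus that of all genes so measured. The median was set among those of 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays. Another 13 lists were written after the first results had been seen.

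Genes were named by a rule, fixed with the lists, that took, among genes with a standard symbol, above background on both arrays and with a mean signal at or above the median, the 12 highest and 12 lowest differences. It added the 4 highest bounds in each direction, the 2 highest and 2 lowest members of each list, Ptprc, Pdpn, Pecam1, H2-Ea and genes for checking sex. Some genes that the rule names are not reported here.

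The only replicate error in the files is that of spots. Over 300 probes printed 10 times, the SD of the log2 difference was 0.14, or 0.063 over 298 probes above background with outlier spots left out. Probes of 1 gene differed more, with a median SD of 0.27 over 7599 genes, and 27 genes had 1 probe at least 2-fold higher and another at least 2-fold lower. Neither error covers differences between mice. Simulated arrays held 22152 genes with noise of the median between-probe SD and 200 changed genes. The 2-fold rule found 98.0% of genes changed by 1.5 on the log2 scale and 100% of those changed by 3. Of unchanged genes, 0.018% passed. These rates follow from the noise that was set, which holds no difference between mice or sorts. They are not error rates of the real comparison, and the 75th percentile of the between-probe SD was 0.50.

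Alternatives were normexp background correction with an offset of 50, quantile and loess normalization (span 0.3), scaling to the median of probes above background on both arrays, no background filter, a stricter signal filter, the mean over a gene's probes, the authors' table, the mean over a list's members, and members above background on both arrays only. The mean over a gene's probes takes in probes not above background. A mean over only the probes above background on both arrays, and a scaling to the median of spike-in probes with a signal under 60000, were added after seeing the data. Whether equal amounts of spike-in RNA were added is not given in the sources used here. Work was done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1.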

Results

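Lymph node stromal cells were profiled on 2 one-color microarrays, 1 array for normal mice and 1 array for mice that carried a 4T1 mammary tumor. 4T1 is a mouse mammary carcinoma line, known as a BALB/c line, while the labels name another strain for the mice. The sample from tumor-bearing mice came from the nodes that drain the tumor, collected 2 weeks after inoculation. Any difference in strain between tumor and host cannot be told apart from other effects of the tumor, with 1 array per group. Both samples were female, and both were sorted as cells without surface CD45, the pan-leukocyte antigen encoded by Ptprc. Each array carried 56605 non-control probes, of which 36783 were well above background on the normal array and 35570 on the tumor-draining array. With 1 array in each group the differences have no replicate check, no p-values are given, and the number of arrays limits the precision. Genes are called higher or lower on the tumor-draining array by size alone, with a difference of at least 2-fold.

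The comparison sets cells sorted as stroma from nodes that drain a primary tumor against those of normal mice. It does not isolate expression within stromal cells, since leukocyte genes were above background on both arrays. Markers of fibroblastic, endothelial and mural stromal cells were lower on the tumor-draining array, and B cell, T cell and pan-leukocyte genes were higher. The median shift relative to all genes was -2.41 on the log2 scale for fibroblastic reticular cell markers, -3.06 for blood endothelial markers, 1.70 for B cell markers and 2.19 for T cell markers. Ptprc, whose product was the marker used to exclude cells from the sort, was 4.91-fold higher on the tumor-draining array, with a signal of 3702 on the normal array and 17432 on the tumor-draining array. Of 22152 genes above background on both arrays, 2453 were at least 2-fold higher and 3532 at least 2-fold lower. A further 365 genes were above background on the tumor-draining array only and 528 on the normal array only, each with a bound of at least 2-fold. The median log2 difference over the 24677 genes above background on at least 1 array was 0.10, and the shifts of gene lists below are relative to it. Spike-in RNA had a median difference of -0.82, so scaling to the spike-ins, chosen after seeing the data, raised every difference by that amount and left shifts of lists relative to all genes as they were. Under it 10357 genes were at least 2-fold higher and 1788 at least 2-fold lower, or 85.3% of calls higher against 41.0%.

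**Figure D1:**
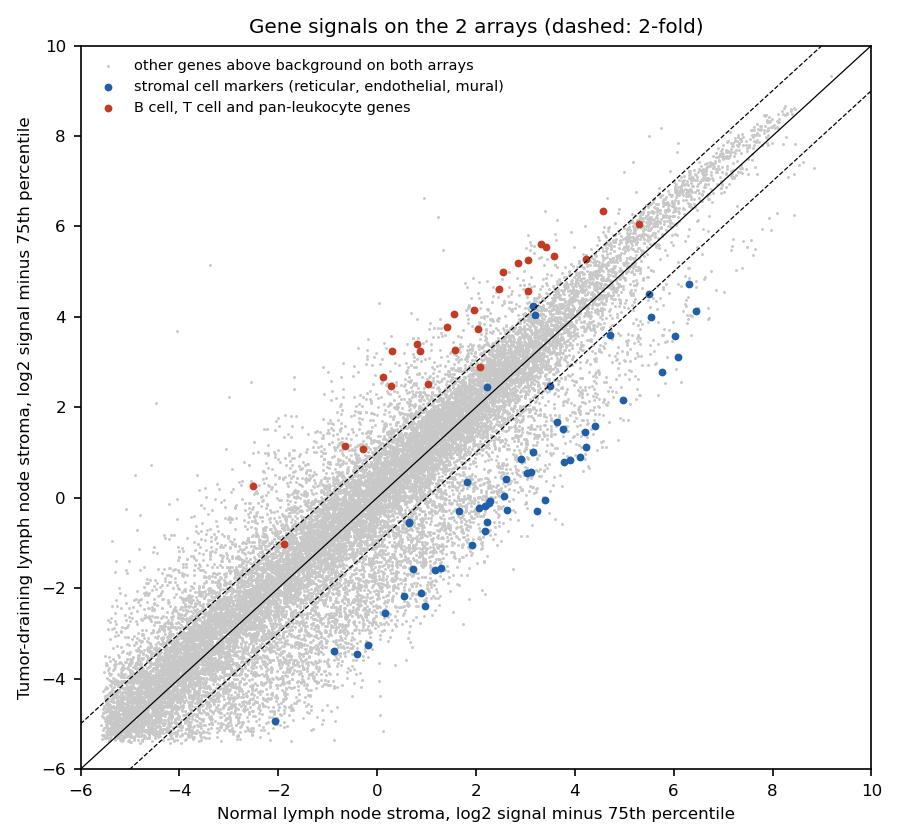
Signal of each gene above background on both arrays, as log2 signal minus the 75th percentile of its array, with the normal array on the horizontal axis and the tumor-draining array on the vertical axis (1 array each), and solid and dashed lines for equal signals and 2-fold differences. Most stromal markers (blue, 48 of 52) lie on or below the lower dashed line, and 24 of the 27 B cell, T cell and pan-leukocyte genes (red) lie on or above the upper one.

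All 13 fibroblastic reticular cell markers were at least 2-fold lower on the tumor-draining array, and 11 of them when scaled to the spike-ins. Ccl19, a chemokine that guides T cells and dendritic cells, was 9.20-fold lower, and Il7, a survival factor for naive T cells, was 8.31-fold lower. Il7 had a difference of -3.06, or -1.78 with normexp background correction. Icam1 and Pdgfra had the smallest differences of the list, at -1.12 and -1.03. Pdpn, the surface glycoprotein used to recognize these cells, was 3.89-fold lower. Its probe lies on chromosome 4 at 142857423 to 142857482, and that of Ccl19 on chromosome 4 at 42250105 to 42250164, in the mm9 coordinates of the array files. The list's median lay below those of all 10000 random lists matched on signal. Of 9 marginal reticular and follicular dendritic cell markers, 6 were at least 2-fold lower and 1 was at least 2-fold higher (2 and 2 when scaled to the spike-ins), with a shift of -1.85. Madcam1, an addressin, had a difference of -2.08 (-0.95 with normexp), and Tnfsf11, the RANK ligand, 0.29. Enpp2, the enzyme autotaxin, had a difference of -2.38, although its probes ranged from -2.38 to 0.54 and their mean was -1.32. Cr2, a complement receptor carried by follicular dendritic cells and by B cells, was 4.38-fold higher. The mean over this list in place of the median gave -1.15. Ptprc was 4.91-fold higher on the same array.

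Most endothelial genes were lower on the tumor-draining array. All 15 blood endothelial markers were at least 2-fold lower (13 when scaled to the spike-ins), among them Emcn (-3.54), a sialomucin of capillaries and veins, and Flt1 (-3.44), a receptor for vascular endothelial growth factor. Pecam1, the adhesion molecule CD31, was 2.25-fold lower, and Ly6c1 had a difference of -1.57. The Pecam1 probe lies on chromosome 11 at 106540864 to 106540923 in mm9. Of 12 lymphatic endothelial markers, 11 were at least 2-fold lower (10 when scaled to the spike-ins), with a shift of -2.60. Prox1, the transcription factor that specifies lymphatic endothelium, was 7.18-fold lower, Flt4 was 7.32-fold lower and Reln was 2.33-fold lower. Nrp2 was 2.14-fold higher on its brightest probe, while its 2 other probes above background on both arrays were at -2.81 and -2.31, and loess gave 0.78. High endothelial venule genes shifted by -1.92, with 7 of 9 genes above background on both arrays at least 2-fold lower, or 4 when scaled to the spike-ins. Ackr1, an atypical chemokine receptor of venules, had a difference of -2.71, Chst4 had one of -0.96 and Gcnt1 one of 0.25. With normexp the venule shift was -1.27, Flt4 had a difference of -0.998 and Chst4 one of -0.21, while loess gave -1.06 for Chst4. Ptprc was 4.91-fold higher on the same array.

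Most mural, adipocyte and matrix genes were lower as well. Pericyte and smooth muscle markers shifted by -2.37, with 9 of 12 at least 2-fold lower, or 7 when scaled to the spike-ins. Kcnj8, a pericyte potassium channel, was 8.33-fold lower, and Des, the muscle intermediate filament desmin, was 10.2-fold lower on its brightest probe, with another probe at 0.42, a mean over its probes of -1.47 and a value of -2.55 with normexp. The list shifted by -1.70 among brighter genes. Cnn1 and Mcam had differences of 0.24 and 0.86. Adipocyte markers shifted by -1.62, from -2.44 for Adipoq, which encodes adiponectin, to 0.12 for Lep (-0.044 after loess), which encodes leptin, among genes above background on both arrays. Of 9 such genes 7 were at least 2-fold lower, or 2 when scaled to the spike-ins. Cidec and Pck1 of that list had differences of -1.92 and -0.91. With normexp Adipoq was at -1.12, Cidec at -1.23 and Pck1 at -0.23, and loess gave -1.01 for Pck1. Of 25 extracellular matrix genes, 21 were at least 2-fold lower (12 when scaled to the spike-ins), with a shift of -1.85. The lowest were Fmod (-3.06) and Tnc (-2.62), and the smallest differences were those of Postn (-0.54) and Lox (-0.48). With normexp Fmod was at -2.40 and Tnc at -1.74. Matrix genes with signals over 50000 on the normal array differed less than dimmer ones, with medians of -1.24 for 6 genes and -1.91 for 19 genes. Activated fibroblast genes shifted by -1.81 (7 of 12 at least 2-fold lower, or 6 when scaled to the spike-ins), with Thbs1 at -2.78, Tgfbi at -2.67, Thy1 at 0.24 (-0.19 after loess) and Tgfb1 at 0.60. Of 12 matrix remodelling enzymes and inhibitors, 11 were at least 2-fold lower (7 when scaled to the spike-ins), including Plau (-2.51), Adamts1 (-2.46) and Mmp11 (-1.05, or -0.99 with normexp). Plaur, the receptor of the Plau product and also a leukocyte gene, was 5.62-fold higher. B cell, T cell and pan-leukocyte genes were higher on the same array.

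Most chemokine, complement and angiogenic genes were lower on the tumor-draining array. In the main setting their list shifts did not exceed those of fibroblastic reticular (-2.41) and blood endothelial markers (-3.06). They therefore cannot be told apart from a lower stromal share. Chemokine and cytokine genes shifted by -2.15, with 13 of 20 genes above background on both arrays at least 2-fold lower, or 11 when scaled to the spike-ins. Cxcl5, a neutrophil attractant, had a difference of -5.26 and Ccl7, a monocyte attractant, -3.40, and with normexp Cxcl5 had a difference of -2.64. Il1b was 4.45-fold higher on its brightest probe, with probes from 0.57 to 2.15 and a mean of 1.55, and Tnf had a difference of 0.93. Complement genes shifted by -2.36 (8 of 11 at least 2-fold lower, or 7 when scaled to the spike-ins), with C2 9.20-fold lower and Cfb 5.80-fold lower, while C1qb and C1qc, which macrophages make, differed by 0.47 and 0.39. The mean over complement genes in place of the median gave -1.69. Angiogenic and lymphangiogenic factors shifted by -1.99 (11 of 13 at least 2-fold lower, or 7 when scaled to the spike-ins), with Apln at -3.80 (-1.47 with normexp), Vegfc at -3.35, Angpt2 at -0.86 (-1.03 after loess) and Vegfb at -0.71. Peripheral tissue antigens and their regulators shifted by -1.21 over 6 measured genes (3 at least 2-fold lower, or 1 when scaled to the spike-ins), from -3.00 for Mlana to -0.34 for Fabp2 and -0.29 for Deaf1. The antigens shifted by -0.88 with normexp and -0.97 without the background filter. Ptprc was 4.91-fold higher on the same array.

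Most B cell and T cell genes were higher on the tumor-draining array. All 8 pan-leukocyte genes were at least 2-fold higher, from Vav1 (1.51) and Was (1.68) to Laptm5 (2.20) and Ptprc (2.30), and the list shifted by 1.66. All 7 Ptprc probes were higher, by 1.04 to 2.67. The probe that stands for the gene lies on chromosome 1 at 139960089 to 139960148 in mm9. Of 10 T cell markers, 9 were at least 2-fold higher, with Cd8a, a coreceptor of cytotoxic T cells, 6.87-fold higher and Cd3g, a chain of the T cell receptor complex, 6.05-fold higher. Cd4 and Cd247 had differences of 1.49 and 0.81, with 1.49 for Cd247 as the mean of its probes, and normexp gave 2.07 for Cd8a. Of 9 B cell markers, 7 were at least 2-fold higher, including Bank1 (2.94) and Cd22 (2.55), while Blk (0.86) and Cd79b (0.76) were within 2-fold. The mean of probes was 1.71 for Cd22. Plasma cell markers shifted by 1.13 and went both ways, with Jchain, the joining chain of IgA and IgM, 17.5-fold higher, Mzb1 3.59-fold higher, Xbp1 at -0.16 and Sdc1 at -0.92 (-1.09 after loess). The plasma cell shift was under 2-fold with normexp background correction (0.56), among brighter genes (0.79) and over members above background on both arrays (0.81). Myeloid cell markers shifted by 0.33, with 1 of 10 at least 2-fold higher, or 8 when scaled to the spike-ins. These ran from Cd14 (-0.68) and Itgam (-0.66) to Adgre1 (0.96) and Tyrobp (1.28). Quantile normalization gave 1.02 for Adgre1, and loess -1.03 for Itgam. Medians of the B cell, T cell and pan-leukocyte lists lay above those of all 10000 random lists, and the myeloid median lay above those of 8303.

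Antigen presentation genes shifted by 0.32, with 5 of 15 at least 2-fold higher, or 9 when scaled to the spike-ins. The 5 were all class II genes. Ciita, the regulator of class II genes, was 7.62-fold higher and H2-Aa, a class II chain, was 5.82-fold higher. Cd74 (2.25), H2-Eb1 (1.77) and H2-Ab1 (1.59) followed. The class I genes H2-K1, H2-D1 and B2m had differences of 0.06, 0.22 and -0.01. B cell markers, with a shift of 1.70, and Ptprc were higher on the same array, so the class II differences cannot be assigned to stromal cells. Tap2 and Gbp2 had differences of -0.17 and -0.11. Immune checkpoint and suppressive genes went both ways, with 4 of 10 at least 2-fold higher and 3 at least 2-fold lower, or 5 and 1 when scaled to the spike-ins. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, and Il10 had differences of 3.05 and 2.08, against -1.94 for Ptgs2 and -1.39 for Nos2. With normexp Il10 had a difference of 0.80 and Pdcd1lg2 one of 2.003. The list's shift of 0.17 turned to -0.21 among brighter genes. Type I interferon-stimulated genes shifted by -0.64, with 4 of 19 at least 2-fold lower and 1 at least 2-fold higher. When scaled to the spike-ins, 1 was lower and 4 were higher. The 4 lower genes included Oasl2 (-2.56) and Rsad2 (-1.45, or -0.97 with normexp), and Oasl1 had a difference of 0.81.

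Erythroid and platelet lists had lower medians. Erythroid markers shifted by -1.15, with Hbb-b1 (-3.04) and Alas2 (-2.77) lowest and Klf1 (-0.81) and Car1 (0.33) highest, while normexp gave 0.11 for Klf1. Platelet markers shifted by -2.68, and of the 4 above background on both arrays Pf4 was 7.30-fold lower, Itga2b was 6.11-fold lower, Gp1bb differed by -0.40 and Gp6 by 0.35. Itga2b was at -1.66 with normexp. The platelet shift was -1.62 over those 4 genes and -0.58 with normexp. The erythroid shift was -0.88 with normexp and -2.92 among brighter genes. Epithelial and mammary carcinoma markers shifted by 0.19, with 10 of 12 within 2-fold (8 were higher when scaled to the spike-ins), including Cldn4 (-0.48) and Krt7 (-0.23). The exceptions were the basal keratins Krt14, which was 4.76-fold higher, and Krt5, which was 3.80-fold higher. Milk protein genes had 3 measured members, Lalba (-0.33), Csn1s1 (-0.09, or 0.062 with normexp) and Csn3 (0.20), all within 2-fold (1 was higher when scaled to the spike-ins), and their shift of -0.18 was 0.034 without the background filter.

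Most genes of lists for general cell functions were within 2-fold. When scaled to the spike-ins, however, 7 cell cycle, 3 oxidative phosphorylation, 16 ribosomal protein, 8 housekeeping, 8 hypoxia and 5 stress genes were at least 2-fold higher. All 22 cell cycle genes were within 2-fold, with a shift of -0.22, from Bub1b and Cdk1 (both -0.49) to Mcm2 (0.57) and Mcm3 (0.76). All 15 oxidative phosphorylation genes were within 2-fold, from Ndufv1 (-0.30) and Cox6c (-0.26) to Cox5a (0.36, or -0.044 after loess) and Cycs (0.73). Their shift was -0.09. All 16 ribosomal protein genes were within 2-fold, with Rps3 (0.28) lowest and Rpl5 (0.75) and Rpl13a (0.92) highest, and their shift of 0.49 was 0.055 after quantile normalization and 0.078 after loess, under which Rps3 turned to -0.28. Housekeeping genes shifted by 0.21, or by -0.039 after quantile normalization, -0.064 after loess and -0.027 in the authors' table. Gusb (-0.74), Tbp (-0.12), Polr2a (0.62) and Gapdh (0.81) marked the ends of that list. Hypoxia and glycolysis genes shifted by 0.40, or by -0.12 after quantile normalization, -0.10 in the authors' table and -0.20 as a mean over members, with Adm (-2.73) and Ndrg1 (-1.32) lowest and Pdk1 (0.92) and Eno1 (0.99, or 1.13 as the mean of its probes) highest. Immediate early and dissociation stress genes shifted by -0.21, from Ier3 (-1.72) and Atf3 (-1.66) to Ier2 (0.72) and Myc, which was 2.01-fold higher but at 0.77 on the log2 scale after loess and 0.94 after quantile normalization.

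**Figure D2:**
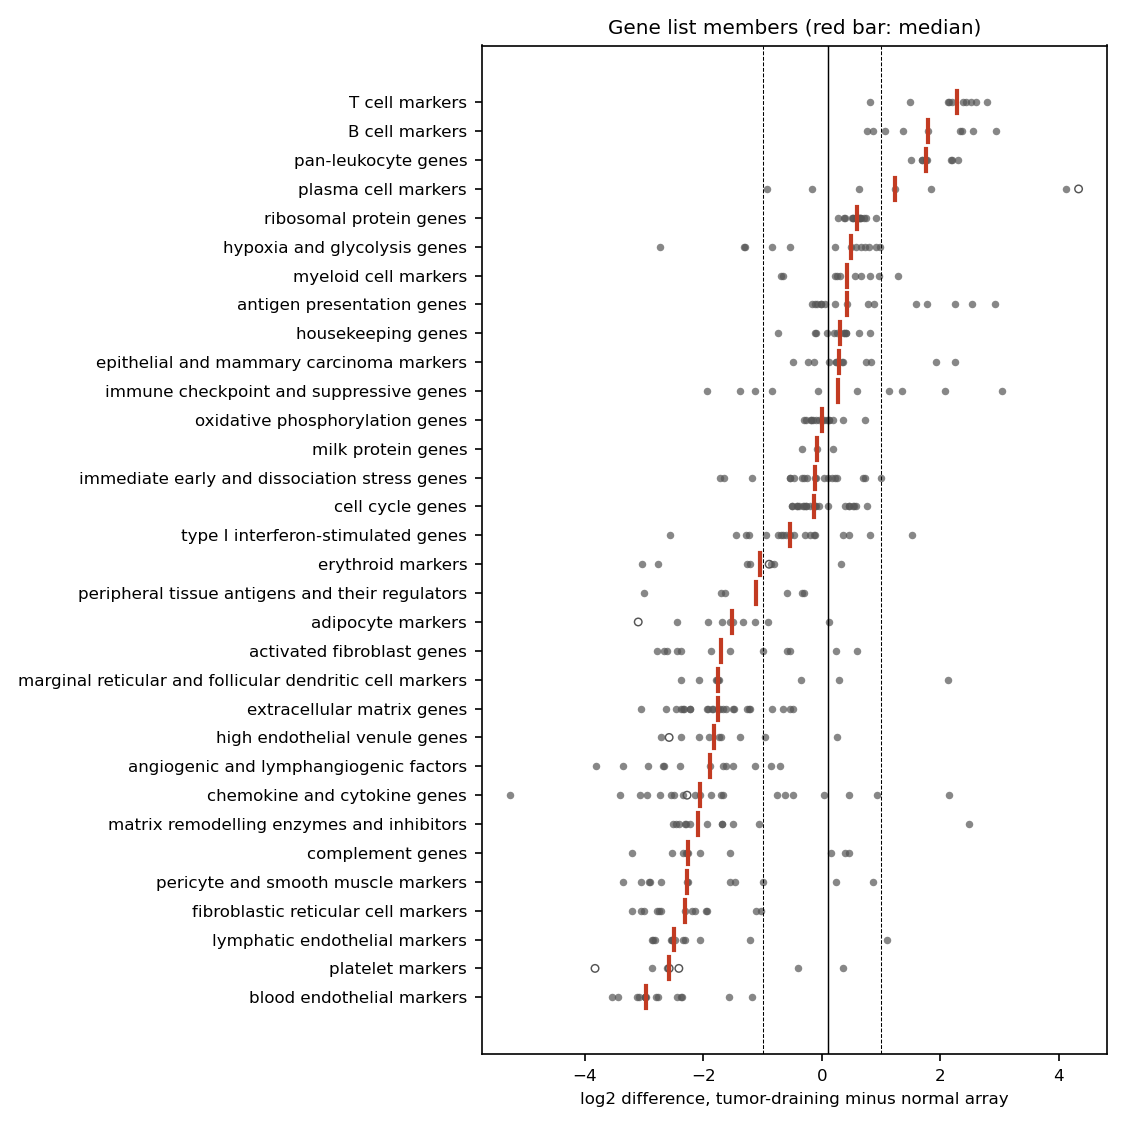
Log2 difference, tumor-draining minus normal array, of each measured member of the 32 gene lists (1 array per group), where filled points are genes above background on both arrays, open points genes above background on 1 array, red bars list medians, the solid line the median of all genes (0.10) and dashed lines 2-fold. T cell markers have the highest median (2.29) and blood endothelial markers the lowest (-2.96).

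Among genes with standard symbols and a mean signal at or above the median, Gpr183, a receptor that positions B cells, was 11.9-fold higher on the tumor-draining array. Ighg3, an immunoglobulin heavy chain constant region, was 9.72-fold higher and Icos, a T cell costimulator, 9.70-fold higher. Cd86, a costimulatory ligand of antigen-presenting cells, was 8.57-fold higher. Izumo1r (3.21), Cxcr5 (3.15), the receptor that directs cells to follicles, Ptpn22 (3.12), Rgs1 (2.97) and Sorl1 (2.96) followed. Slpi, a secreted protease inhibitor, was 51.0-fold higher on its brightest probe on chromosome 2 at 164179849 to 164179908 (mm9), but another probe of the gene had a difference of 0.78. Syt10, a synaptotagmin, was 20.5-fold higher on 1 probe, while its other probe was not well above background on either array. The mean over the probes above background on both arrays gave 3.22 for Slpi, in place of 5.67. The lowest differences were those of F3, which encodes tissue factor and was 20.1-fold lower, Agtr2, an angiotensin receptor (-4.32), and Cyp2f2, a cytochrome P450 (-4.31). Gli1 and Hhip, both targets of Hedgehog signaling, had differences of -4.15 and -4.10. With normexp Gpr183 was at 2.93, Syt10 at 3.70, Agtr2 at -3.58, Gli1 at -3.51 and Hhip at -3.32. Chrdl1 (-4.06), Pcsk6 (-3.86), Pcolce2 (-3.82), Meox2 (-3.77), Cyp26b1 (-3.74), an enzyme that degrades retinoic acid, Fndc1 (-3.63) and Gstt1 (-3.60) followed.

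Some genes were well above background on 1 array only and have a bound in place of a difference. Tigit, an inhibitory receptor of T cells, was at least 15.1-fold higher on the tumor-draining array, Hpgds at least 12.2-fold and Klk10 at least 8.36-fold. On the normal array, Atp6v0a4 was at least 16.1-fold higher, Cldn22 at least 15.4-fold, Bmp5 at least 14.7-fold and Pla2g5 at least 12.9-fold.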

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

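Scaling to the spike-ins and the mean of a gene's measured probes, those above background on both arrays, were chosen after seeing the data. Of 316 list shifts under the other alternatives, 237 moved by less than the spot error of 0.14 and 79 by more. The 237 include the values of all 32 lists under median scaling, which leaves list shifts as they are by construction. The authors' table follows quantile normalization, so these 2 alternatives are not independent. All 197 values of lists with a main shift of at least 2-fold kept their sign, and no named gene with a difference of at least 2-fold turned its sign in 564 values, although Nrp2 turned to -1.34 as the mean of its measured probes. Smaller differences of Klf1, Csn1s1, Car1, Lep, Thy1, Cox5a and Rps3 turned their sign under at least 1 of the other alternatives. Filters leave single genes' differences as they are by construction, and median scaling moves all of them by the same small amount. Genes at least 2-fold higher numbered 1374 with normexp, 4138 with no background filter and 813 with the stricter filter, against 2453. Genes at least 2-fold lower numbered 5344 with no filter and 1127 with the stricter one, against 3532. The filters also change how many genes are admitted, 37008 with no filter and 9914 with the stricter one, against 24677. Other causes of these counts were not tested. Scaled to the spike-ins, 10357 were higher, 1788 lower, 962 on the tumor-draining array only and 180 on the normal array only, since every difference is raised by the same amount by construction. Genes above background on 1 array only with a 2-fold bound dropped with normexp to 17 on the tumor-draining and 19 on the normal array. This setting changes the background correction and adds an offset of 50, and the part of each was not tested. The median difference of all genes, 0.10, was -0.09 after loess and 0.92 scaled to the spike-ins. Differences of dim genes are limited by their signal over background. No paired analysis was possible because each group has 1 array, which also rules out leaving out an array.

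With normexp, shifts were -2.13 for fibroblastic reticular, -1.51 for marginal reticular and follicular dendritic, -2.15 for lymphatic endothelial and -2.57 for blood endothelial markers. They were -1.27 for high endothelial venule genes, -2.10 for pericyte, -1.13 for adipocyte, 1.51 for B cell, 0.56 for plasma cell, -0.88 for erythroid and -0.58 for platelet markers. They were -0.01 for milk protein genes, -1.53 for activated fibroblast genes, -1.72 for both matrix enzymes and chemokines, -1.49 for angiogenic factors and -0.88 for peripheral tissue antigens. Quantile normalization gave -2.72 for fibroblastic reticular markers, -2.004 for matrix genes, -1.95 for activated fibroblast genes and -0.12 for hypoxia genes. It gave -0.26 for oxidative phosphorylation, -0.62 for stress, 0.055 for ribosomal protein and -0.039 for housekeeping genes. Loess gave -2.66 for fibroblastic reticular markers, -2.01 for matrix, 0.09 for hypoxia, -0.28 for oxidative phosphorylation, -0.54 for stress, 0.078 for ribosomal protein and -0.064 for housekeeping genes. The authors' value table gave -2.66, -0.10, -0.27, -0.61, 0.10 and -0.027 for fibroblastic reticular, hypoxia, oxidative phosphorylation, stress, ribosomal protein and housekeeping genes.

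No background filter gave 0.034 for milk protein genes, 0.44 for checkpoint genes and -0.97 for peripheral tissue antigens. The stricter filter gave -1.70 for pericyte, 2.19 for B cell, 2.05 for T cell, 0.14 for myeloid, 0.79 for plasma cell and -2.92 for erythroid markers. It gave -1.83 for matrix enzymes, -0.44 for interferon-stimulated genes, -2.49 for chemokines, -0.21 for checkpoint genes, -2.53 for angiogenic factors and 0.08 for hypoxia genes. The mean of a gene's measured probes gave -2.03 for pericyte, 1.46 for B cell, -2.19 for complement and -0.38 for stress genes. The mean of all of a gene's probes, dim ones included, gave -1.44 for marginal reticular, -1.96 for pericyte and 1.46 for B cell markers, 0.52 for antigen presentation and -2.04 for complement genes, -0.38 for stress genes and -0.86 for peripheral tissue antigens. The mean of the members gave -1.15 for marginal reticular, -2.22 for lymphatic and -2.81 for blood endothelial, -1.97 for pericyte, 1.49 for plasma cell, -1.41 for erythroid and -2.15 for platelet markers. It gave 0.42 for epithelial markers, -1.56 for activated fibroblast genes, -1.73 for matrix enzymes, 0.77 for antigen presentation genes and -1.76 for chemokines. It gave -1.69 for complement genes, -2.19 for angiogenic factors, -0.20 for hypoxia genes and -1.36 for peripheral tissue antigens. Members above background on both arrays gave 0.81 for plasma cell, -1.33 for erythroid and -1.62 for platelet markers. The cause of these movements was not tested.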

Other observations

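The 13 gene lists in this paragraph and the next were written after the first results had been seen, as their named members were chosen, and the tests of explanations below were chosen after the results they bear on. Several of these lists hold genes already seen among the results, so their shifts are given without those genes too. Genes of germinal center B cells shifted by 2.94 (2.31 without them), with Rgs13 39.4-fold higher on the tumor-draining array and Gcsam 12.7-fold higher. S1pr2 was at -0.14 and Fas at 0.12 and 1.41 on its 2 probes. The folds of Rgs13 and Gcsam rest on normal-array signals of 15.7 and 9.44, where the lowest signal above background was 7.72. Follicular helper T cell genes shifted by 2.63 (2.40 without genes already seen), with Pdcd1 6.41-fold higher and Sh2d1a 6.82-fold higher. Il21 was at 0.09 and Bcl6 at 0.67 and 1.12 on its 2 probes. Regulatory T cell genes shifted by 2.42 (2.31 without them), with Foxp3 6.17-fold higher and Ctla4 17.6-fold higher. Natural killer and cytotoxic genes shifted by 2.06, with Gzmb 5.91-fold higher, and naive T cell genes by 1.51, with Ccr7 4.59-fold higher. Mast cell and basophil genes shifted by 1.16, where the basophil proteases Mcpt8 and Prss34 were 6.74-fold and 4.51-fold higher and the mast cell proteases Cma1 and Tpsb2 differed by -0.18 and -0.49. Of the immunoglobulin constant region genes 1 was measured, Ighg3 (3.28).

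Neutrophil genes shifted by 0.36, from Ly6g (-1.51) to Mmp8 (1.59), and dendritic cell genes by -0.20, from Zbtb46 (-2.54, with another probe at -1.21) to Ccr9 (2.09). Hedgehog pathway genes shifted by -2.27 (-2.17 without genes already seen), with the receptor Smo 4.55-fold lower and Ptch1 at -0.08 on its brightest probe and at -1.34 on another. Retinoid pathway genes shifted by -1.41 (-1.05 without them), with Aldh1a3 9.04-fold lower and Aldh1a1 at 0.26. Schwann cell and nerve genes shifted by -2.22 (-2.55 without them), with S100b 18.1-fold lower and Sox10 at -0.15. Fibroblastic reticular and pericyte markers shifted by -2.41 and -2.37. The Hedgehog, retinoid and Schwann cell shifts therefore cannot be told apart from a lower stromal share, which was not tested. Keratinocyte and basal epithelial genes shifted by 0.91, but by -0.48 without Krt14 and Krt5, which had been seen as higher, with Trp63 2.02-fold higher on its brightest probe (0.16 on another), Sfn 2.57-fold higher and Lor 3.43-fold lower.

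Stromal markers were lower and lymphocyte markers higher, with medians of -2.53 over 52 stromal and 2.19 over 19 B cell and T cell genes, a gap of 4.72 (95% bootstrap interval over genes, which are not replicates, 3.99 to 5.15). The smallest gap under normexp, quantile or loess was 4.31, so the choice among these settings does not account for it. Scaling an array by a constant leaves the gap as it is by construction. The T cell median exceeded the myeloid one by 1.85 (1.30 to 2.38), so these 2 lists did not rise alike. Whether a lower stromal share that raised every other cell type alike had a part cannot be told from this. The T cell list defines the pattern, and the interval is over genes, with 1 array per group. A sort for cells without CD45 would be meant to remove lymphocyte RNA. Of 27 B cell, T cell and pan-leukocyte genes, 88.9% were at least 2-fold higher, but these include the markers that define the pattern. Outside it, all 8 natural killer and cytotoxic genes and 5 of 7 naive T cell genes were at least 2-fold higher. None of these was 2-fold lower, though both lists were written after the first results. Lymphocyte genes thus had higher signals relative to all genes on the tumor-draining array. The source of this lymphocyte RNA cannot be told apart from other causes of the pattern, with 1 array per group. All 27 were above background on the normal array too, no other planned list holds any of them, and Coro1a, 1 of them, had signals of 8844 and 28909. Lower expression within stromal cells, or a biological effect of the tumor on the makeup of the node, stays open and was not tested, since each group has 1 array.

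Bright matrix genes differed less than dimmer ones, by 0.68 (0.31 to 1.37). Spike-in RNA, added to both samples, had differences of -0.97 to -0.76 over 6 probes under a signal of 60000, while the 2 brighter ones, at 75617 and 164676 on the normal array, lay 0.30 and 0.71 above their median. Compression of the brightest signals cannot be told apart from other causes, since few spike-ins reach these signals and the one at 50726, just under the dimmest of the 6 bright matrix genes (53861), had a difference of -0.86. A smaller change of abundant matrix genes in the uncompressed range cannot be told apart from none, since genes of 5000 to 50000 lay 0.29 above those under 5000, with an interval of -0.66 to 0.79. Probes of Sparc ranged from -2.16 to 0.63 and those of Col1a1 from -2.06 to 0.86, while those of Col3a1 ranged from -2.42 to -0.85, of Fn1 from -2.44 to -1.61 and of Col1a2 from -1.27 to -0.35.

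The H2-Ea probe, on chromosome 17 at 34481469 to 34481528 (mm9), was above background on both arrays, at 557 on the normal and 2836 on the tumor-draining array, a difference of 2.41. The labels name C57BL/6 mice, a strain known not to transcribe H2-Ea, and 4T1 is known as a BALB/c line. If the label is right, tumor and host differed in strain. Whether they did, and whether this had a part in the lymphocyte and other differences between the arrays, was not tested. Whether the probe also binds another class II transcript was not tested. Of the genes for checking sex, Xist had signals of 384 and 299 and Kdm5d of 73.4 and 49.0, and Ddx3y, Uty and Eif2s3y were not well above background on either array. Itsn1, chosen after its values were seen, was 2.77 higher on its brightest probe, while its 5 other probes above background on both arrays were lower.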
